A study of Homo sapiens with 6 samples.

How the data were processed

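ATAC-seq libraries from U937 cells were analysed from the peak lists that the authors deposited, 1 list for each of 6 libraries. Groups and replicate numbers came from the sample titles: 3 control lines and 3 ΔNSPs clones. Per the labels, the clones were independent, and cells of both groups were treated with DNase, washed and cryopreserved in a DMSO medium before ATAC-seq at a service laboratory. P-values of values per library measure the spread between these libraries, and those of gene lists and genome bins do not. The labels name no library batch, so a batch that followed the groups could not be separated from them.

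Per the submitters' processing notes, the tools used were FastQC, Bowtie2, Picard and MACS2, with build GRCh38. Their versions, settings and roles, and whether reads were shifted for the transposase offset, are not given in the sources used here. Each deposited list held the peaks of a single library, with library names in the peak names, so peaks were called per library and not on pooled reads. For each summit the authors' lists give a fold enrichment, as a ratio over the local background, and −log10 values of p and q. The score the authors deposited is the integer part of 10 times the −log10 q, as tested on the values, and was not used. The lowest −log10 q was just above 2 in each list (2.07, 2.04 and 2.02 in control lines 1, 2 and 3, and 2.00 in each clone). The lowest −log10 p differed, at 7.45, 7.79 and 8.00 in control lines 1, 2 and 3 and 4.89, 4.86 and 5.75 in clones 1, 2 and 3. A peak therefore needed a smaller p to enter a control list than a clone list. A summit offset below 0 in 127 lines of the list of clone 2 was set to 0.

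Lines that share an interval, as several summits of a peak do, were counted as 1 peak with its highest summit. The lists had 53, 26 and 14 lines in control lines 1, 2 and 3 and 18668, 27937 and 2547 in clones 1, 2 and 3. Peaks on chromosomes 1-22, X and Y entered the comparisons, 13, 4 and 2 in the control lines and 14262, 24981 and 2188 in the clones. Regions were the union of the 6 lists, merged where peaks overlapped by 1 bp or more. Peaks were ranked within a list by −log10 q. Fold enrichments were used to describe peaks, as a filter in an alternative, and with the p to solve the pile-up and background compared between libraries.

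No genome sequence was used here, and the gene table (GRCh38.p14, RefSeq) gave gene starts and ends without strand or exons. The planned promoter window around transcript 5′ ends was therefore replaced by a window of 1000 bp either side of both ends of each gene, over 19974 protein-coding genes on chromosomes 1-22 and X. Positions were classed by the summit as gene end, gene body or intergenic, over protein-coding and long non-coding genes, as were the regions away from gene ends. Motif enrichment was not run, for want of a sequence. Random placements kept each peak's width and chromosome (100 placements), with the chromosome's length taken as the highest gene or peak coordinate on it.

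The pile-up and background behind each peak were solved from the fold, as (pile-up + 1)/(background + 1), and the p, as a Poisson tail. This gave whole pile-ups, within 0.05 read, for 100% of the peaks in each of the 6 lists. On 1862 simulated peaks the pile-up was recovered for 100%. The simulation used the same formulas and did not reach the largest pile-ups and backgrounds reported below, so it does not check those. The read totals stay unknown, so no floor or interval that needs them was given.

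Peaks, covered length and genes with a gene-end peak per library were compared on log10(value + 1) with an exact two-sided permutation test over 20 assignments, whose smallest p is 0.1. Regions and genes called in at least 2 of 3 clones and in no control line were counted, with the reverse count and the other splits of the 6 libraries beside them. Each of 19 gene lists, fixed before the data were examined, was tested with a two-sided Fisher's exact test against all other protein-coding genes, on having a gene-end peak in at least 2 of 3 clones, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Of 920 list symbols, 918 matched the gene table. Genes are not replicates, so these p-values measure chance membership, not variation between clones. In 100 simulated runs over 19974 genes, lists planted at an odds ratio of 4 were called in 99 runs (histone genes) and 100 runs (ribosomal protein genes), and 0.353% of the lists planted without a difference were called. The simulation drew genes independently, so it does not cover lists whose members share peaks. It planted a difference only in these lists of 69 and 79 members, so it does not give the power for the smaller lists. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only.

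The genes named were set by rule before the data were examined. They were the 3 targeted genes, genes with a control gene-end peak, the 12 genes with the smallest sum of ranks among those called in all 3 clones and no control line, up to 4 members of each list with peaks in the most clones and up to 2 with none, the 5 best distal regions, and regions called in at least 2 control lines. Some items that the rule takes are not reported here. Alternatives included a −log10 q or fold of 5 or more, windows of 500 and 2500 bp, an overlap of 50% of both peaks, all 3 clones, equally long lists, all sequences, the replicate numbers as a block and leaving out each library. Added after seeing the data were windows of 100 bp around summits, Mantel-Haenszel odds ratios within chromosomes and within classes of gene density (genes within 500 kb), and the removal of unevenly covered segments. The Mantel-Haenszel p came from a chi-square with continuity correction. An exact conditional test over the same strata was added after those p-values had been seen, because the lists are small, and both are reported. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.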

Results

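Chromatin accessibility was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA. The cells were U937, an established human monocytic line from a histiocytic lymphoma. Control plasmids had been introduced into 3 control lines. In 3 independent clones, called ΔNSPs, the neutrophil serine proteases cathepsin G (CTSG), neutrophil elastase (ELANE) and proteinase 3 (PRTN3) had been depleted together. The comparison asked which sites were accessible in cells without these proteases and in control cells. Each library was represented by its own list of peaks, on build GRCh38, with a fold enrichment, a −log10 p and a −log10 q per peak that were the authors' own values. A list holds no value for a site without a peak, so sites were compared by whether a peak was listed, not by signal level. Read totals were not given, so the depth of each library was not known directly. The pile-up and local background that the fold and −log10 p imply had a median background of 5.90, 3.55 and 7.19 reads over the peaks of clones 1, 2 and 3, and of 2.71 and 3.72 reads over the 13 and 4 peaks of control lines 1 and 2. Control line 3 had only 2 peaks, with a background of 1285 reads on chromosome 3 and 3.16 reads on chromosome 18. These medians cover different sites in each library. The lowest implied background in clones 1, 2 and 3 was 1.22, 0.878 and 1.41 reads, reached by 113, 756 and 60 peaks. In control lines 1, 2 and 3 the lowest was 1.35, 1.18 and 2.82 reads, reached by 1 peak each. The lowest background rises with depth and with the unknown extension length of the peak caller. The shortest peaks of the 3 clones were 115, 61 and 108 bp, and those of control lines 1, 2 and 3 were 100, 113 and 111 bp. Peaks within 1000 bp of either end of a protein-coding gene are called gene-end peaks here, since the annotation used gave no strand and the 5′ and 3′ ends of a gene could not be told apart.

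The depleted genes themselves carried few peaks. ELANE (chromosome 19, 852303 to 856243) and PRTN3 (chromosome 19, 840999 to 848175) had no gene-end peak in any of the 6 libraries. CTSG (chromosome 14, 24573518 to 24576250) had a gene-end peak only in clone 2, at 24576267 to 24576452, 17 bp outside the gene, with a fold enrichment of 3.20 and a −log10 q of 2.83. That peak was not among those with a −log10 q of 5 or more. The nearest peak to ELANE lay 36.9, 16.6 and 54.9 kb away in clones 1, 2 and 3. Depletion of the proteins is not measured by ATAC-seq, so these values do not check the genotype.

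Peaks were abundant in the ΔNSPs clones and nearly absent from the control lines. On chromosomes 1-22, X and Y, clones 1, 2 and 3 had 14262, 24981 and 2188 peaks, and control lines 1, 2 and 3 had 13, 4 and 2. The mean was 13810 ± 11403 peaks (SD, n = 3) in the clones against 6.33 ± 5.86 (SD, n = 3) in the control lines, with an exact two-sided permutation p = 0.1 on log10(peaks + 1), the smallest value that 3 libraries against 3 allow. The difference of the group means was 3.19 on that log10 scale. The clone with the fewest peaks had 168-fold more than the control line with the most. Over all sequences in the files this ratio was smaller. Clones 1, 2 and 3 then had 14280, 25052 and 2200 peaks, and control lines 1, 2 and 3 had 36, 14 and 12. Among the clones, peak number differed 11.4-fold. Peaks covered 4338, 2986 and 439 kb in clones 1, 2 and 3 and 2.71, 1.04 and 0.412 kb in control lines 1, 2 and 3. Gene-end peaks were present at 7813, 5909 and 1308 of 19974 protein-coding genes in clones 1, 2 and 3, and at 1, 0 and 0 genes in the control lines. For covered length and for genes, the exact permutation p was again 0.1 (n = 3 per group). Sequence outside chromosomes 1-22, X and Y held 63.9, 71.4 and 83.3% of the peaks of control lines 1, 2 and 3, and 0.126, 0.283 and 0.545% of those of clones 1, 2 and 3.

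**Figure D1:**
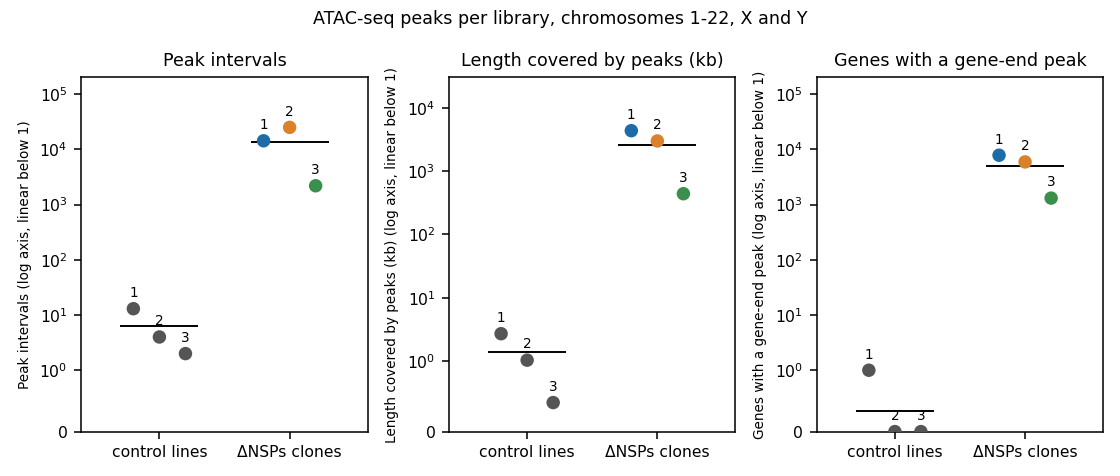
Peaks per library on chromosomes 1-22, X and Y, as the number of peaks, the length they cover in kb and the number of protein-coding genes with a gene-end peak, each on a log axis that is linear below 1. Points are libraries labelled by replicate number and bars are group means (n = 3); the clones span 2188 to 24981 peaks and the control lines 2 to 13.

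Merging the 6 lists gave 32822 separate regions. Of these, 6874 had a peak in at least 2 clones, and 6872 of them had none in any control line. With only 16 regions holding a control peak, that count was nearly fixed by the short control lists. In reverse, 0 regions had a peak in at least 2 control lines and in no clone, but only 2 regions had a peak in at least 2 control lines. All 3 clones shared 1253 regions, none with a control peak. A peak in 1 clone alone and in no control line was found at 7630 regions for clone 1, 17859 for clone 2 and 445 for clone 3. At genes, 4652 of 19974 (23.3%) had a gene-end peak in at least 2 clones and in no control line, 1079 in all 3 clones, 4647 in 1 clone and 10675 in none. The condition on the control lines removed none of the 4652, since only 1 gene had a control gene-end peak. The counts depended on the threshold: with a fold enrichment of 5 or more, 225 regions and 135 genes were left. Without clone 1 the counts were 1439 regions and 1124 genes, and without clone 2 they were 1470 and 1240, since both remaining clones then had to share the site.

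A control peak lay at 16 regions, and 8 of these also held a peak of a clone. Of the 19 control peaks, 11 overlapped a peak of any clone (57.9%, exact Clopper-Pearson 95% interval 33.5 to 79.7, counting error only). That interval takes the 19 peaks as independent, but they lay at the 16 regions, some of them called in more than 1 control line. All 3 control lines shared a region on chromosome 3, at 93470379 to 93470762, outside any protein-coding gene and 402443 bp from PROS1. The implied pile-up there was 1723, 2793 and 2217 reads in control lines 1, 2 and 3, and 1956 and 3582 reads in clones 1 and 3. The implied background was high as well, at 1495, 1304 and 1285 reads in the control lines and 1575 and 1912 reads in clones 1 and 3. The folds were therefore low, at 1.15, 2.14 and 1.72 in the control lines and 1.24 and 1.87 in clones 1 and 3. Control lines 1 and 3 shared a region on chromosome 18, at 106880 to 107595, which was also called in clone 1. The gene with a control gene-end peak was PLEKHF2, at chromosome 8, 95133643 to 95133758, in control line 1, with a fold of 2.78; clone 1 had a separate peak at 95133778 to 95133916, with a fold of 3.92. Over all sequences in the files, 11 regions were called in at least 2 control lines, and 2 of them lay on chromosomes 1-22, X and Y.

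The clones shared sites far more often than random placement on the same chromosomes gave. Of clone 3 peaks, 67.9% overlapped a clone 1 peak by 1 bp or more and 65.9% a clone 2 peak, against 0.365% and 0.447% of randomly placed peaks. Of clone 1 peaks, 44.9% overlapped a clone 2 peak, against 0.427% by chance. The highest value in 100 random placements was 0.823% over the 3 pairs. In total, 79.6% of clone 3 peaks were found in clone 1 or clone 2. When gene-end peaks were placed only at gene ends and the others elsewhere, the mean overlap was 23.7-fold over chance, in place of 146-fold.

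By position, with windows at the ends of long non-coding genes added to those of protein-coding genes, gene ends held 56.1%, 27.7% and 50.8% of summits in clones 1, 2 and 3. With protein-coding genes alone, 51.8, 23.4 and 47.4% of the peaks touched a gene-end window. With long non-coding genes included, the mean share of summits at gene ends over the clones was 44.9% ± 15.1 (SD, n = 3), 8.45 ± 2.80-fold above random placement. Gene bodies held 34.0% ± 9.05 of summits and intergenic sequence 21.2% ± 6.43 (SD, n = 3), 0.660 ± 0.179 and 0.489 ± 0.145 times the random share. Peaks were narrower in clone 2, with a median width of 99 bp against 251 and 171 bp in clones 1 and 3. In control line 1, 1 of 13 summits lay at a gene end (7.69%, exact Clopper-Pearson 95% interval 0.195 to 36.0), and control lines 2 and 3 had none of 4 and none of 2.

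Among genes with a gene-end peak in all 3 clones and no control line, those with the highest ranks of −log10 q within the clones' lists were named by a fixed rule. The first was PDK1, a kinase that inhibits pyruvate dehydrogenase, with a peak at chromosome 2, 172555407 to 172556887, in clone 1 and folds of 3.99, 3.64 and 2.51 in clones 1, 2 and 3. The median folds over the peaks of clones 1, 2 and 3 were 3.54, 4.16 and 3.35. PDK1 thus lay below the median in clones 2 and 3, so a high rank did not mean a high fold. USP5, a deubiquitinating enzyme whose peaks were also counted for CDCA3, had folds of 4.49, 6.14 and 3.17 in clones 1, 2 and 3. Its clone 2 value came from a peak at 6851308 to 6851477. That peak did not overlap those behind the values of clone 1 (6852327 to 6852662) and clone 3 (6851945 to 6852538). TBC1D23 had folds of 3.65, 6.43 and 2.43, and MAN1B1, an alpha-mannosidase of glycoprotein processing, of 4.46, 8.54 and 3.15. AGFG2 (2.69, 4.08 and 2.67, below the median fold in each clone) and TOMM40, the channel of the mitochondrial outer membrane import complex (3.82, 4.28 and 2.60), followed the same rule. KHSRP and SLC25A41 shared a single peak between them, with folds of 3.62, 4.64 and 3.09, and INPP5K and PITPNA shared another, with 5.30, 7.86 and 3.47. EIF4A1, a translation initiation helicase, had folds of 3.34, 5.51 and 3.08, the value in clone 3 coming from a peak at its other end that was also counted for CD68.

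Housekeeping gene groups fixed before the data were examined had gene-end peaks more often than other genes. Cytoplasmic ribosomal protein genes had one in at least 2 clones at 43 of 79 genes (54.4%, against 23.2% of all other genes; odds ratio 3.96, two-sided Fisher's exact test, adjusted p = 2.75e-08 over 19 lists). The shares in clones 1, 2 and 3 were 73.4, 64.6 and 21.5%. RPL18 had folds of 3.42, 4.65 and 2.55 in clones 1, 2 and 3, in a peak shared with SPHK2; RPL11 and RPS27A had none in any clone. Replication-dependent histone genes had a gene-end peak in at least 2 clones at 35 of 69 genes (odds ratio 3.41, Fisher's exact adjusted p = 5.59e-06). Neighbouring histone genes shared peaks, for example H2AC12 and H2BC12 with folds of 4.24, 4.39 and 3.79, and the 35 genes formed 22 groups that shared no peak, so the members were not independent. The odds ratio was above 1 in 3 of 3 clones for both lists. With the clones reduced to equally long lists, ribosomal protein genes no longer passed the threshold (Fisher's exact adjusted p = 0.0944).

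Cell cycle genes had a gene-end peak in at least 2 clones at 15 of 30 genes (odds ratio 3.30) and lysosome and phagosome genes at 14 of 27 (odds ratio 3.55), each with a Fisher's exact adjusted p of 0.00739 and an odds ratio above 1 in 3 of 3 clones. Among cell cycle genes, CDK2 had folds of 2.47, 4.78 and 2.42 in clones 1, 2 and 3, in peaks within the window of RAB5B as well. PCNA, the sliding clamp of DNA replication, had folds of 3.51 and 3.35 in clones 1 and 2, and CCNA2 and CCND1 had none in any clone. Among lysosome and phagosome genes, VPS35, a retromer subunit, had folds of 3.79, 3.41 and 3.15, and ATP6V0D1, a proton pump subunit, of 4.03, 5.55 and 4.35 in clones 1, 2 and 3, while LAMP2 and CTSA had none. Neither list passed the threshold without clone 1 (Fisher's exact adjusted p = 1 and 0.297, odds ratios 1.20 and 2.92), with a −log10 q of 5 or more (0.0627 and 0.0883), with a peak in all 3 clones (1 and 0.262) or with equally long lists (0.683 each). Without clone 2 cell cycle genes did not pass (Fisher's exact adjusted p = 0.428, odds ratio 2.33). Over all alternatives the odds ratio was 1.20 to 3.68 for cell cycle genes and 2.43 to 4.58 for lysosome and phagosome genes. Chromatin remodelling and histone modifying genes had a gene-end peak in at least 2 clones at 15 of 40 genes, which did not pass the threshold (odds ratio 1.98, Fisher's exact adjusted p = 0.0751). With a window of 2500 bp this list passed (odds ratio 2.44, Fisher's exact adjusted p = 0.0197), and in the other alternatives it did not. Members included SMARCC1, a subunit of the SWI/SNF remodelling complex, with folds of 3.93 and 7.23 in clones 1 and 2, and KDM1A, with 3.11, 3.61 and 3.63 in clones 1, 2 and 3.

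Of the myeloid, immune and leukaemia-associated gene lists, none passed the test for more gene-end peaks in at least 2 clones than other genes, and macrophage genes passed it for fewer. Myeloid transcription factors had one in at least 2 clones at 6 of 20 genes (odds ratio 1.41, Fisher's exact adjusted p = 0.519). EGR1 had folds of 5.44, 4.14 and 2.71 in clones 1, 2 and 3, and SPI1, which encodes PU.1, and CEBPD had none. Monocyte surface and effector genes had 3 of 28 (odds ratio 0.395, Fisher's exact adjusted p = 0.257), the 3 being ITGAM, CCR2 and FCGR2A; in clones 1, 2 and 3 they were 6, 9 and 0 (odds ratios 0.424, 1.13 and 0). Azurophil granule proteins, the group to which the depleted proteases belong, had 1 of 16 (odds ratio 0.219, Fisher's exact adjusted p = 0.223), which was RNASE2, with folds of 4.42 and 4.82 in clones 1 and 2. The clones went apart in that list, with 1 of 16 in clone 1 (odds ratio 0.104), 6 of 16 in clone 2 (37.5%, odds ratio 1.43) and 0 in clone 3. Macrophage genes had 1 of 26 (odds ratio 0.132, Fisher's exact adjusted p = 0.0419), which was CD68, whose peak was also counted for EIF4A1. Interferon-stimulated genes had 7 of 29 (odds ratio 1.05, Fisher's exact adjusted p = 0.876), among them MX2 in all 3 clones, and IFIT1 and IFIT2 had none. NF-kB and inflammatory cytokine genes had 6 of 30 (odds ratio 0.823, Fisher's exact adjusted p = 0.876), with RELB and CCL5 among them and none at IL1A or IL6. Antigen presentation genes had 8 of 23 (odds ratio 1.76, Fisher's exact adjusted p = 0.273), with TAP1 and B2M among them and none at CIITA or CD74. The HOXA cluster and leukaemia-associated cofactors had 3 of 16 (odds ratio 0.760, Fisher's exact adjusted p = 1), namely PBX3, HOXA13 and HOXA9. Where a gene was counted in 2 clones, the peaks could lie at its opposite ends, as for FCGR2A and RELB.

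Genes of other tissues and lineages had few gene-end peaks, but this was not particular to them. Macrophage, azurophil granule and monocyte genes had odds ratios below 1 too (0.132, 0.219 and 0.395), although of these only macrophage genes passed the test. Those values were not as low as for olfactory receptor genes (0.00821) or for hepatocyte and epithelial, neuronal and glial, and B cell markers (0 each). In clone 2, azurophil granule and monocyte genes were above 1 (1.43 and 1.13), while the lists of other tissues and lineages were below 1 in every clone. Olfactory receptor genes had one in at least 2 clones at 1 of 392 genes (odds ratio 0.00821, Fisher's exact adjusted p = 7.25e-43), with an odds ratio below 1 in every clone, and the gene was OR52W1. Hepatocyte and epithelial markers had 0 of 20 (Fisher's exact adjusted p = 0.0225), with no gene-end peak in any clone, and neuronal and glial markers had 0 of 18 (adjusted p = 0.0313), although 2 of them had one in clone 1 alone and 3 in clone 2 alone. With a window of 2500 bp neuronal and glial markers did not pass (odds ratio 0.158, Fisher's exact adjusted p = 0.111), while B cell markers did (adjusted p = 0.0226). With 1000 bp, B cell markers had 0 of 16 (Fisher's exact adjusted p = 0.0679), T and NK cell markers 2 of 20 (odds ratio 0.366, adjusted p = 0.263), which were NKG7 and CD3E, and erythroid and megakaryocyte markers 1 of 19 (odds ratio 0.183, adjusted p = 0.168), which was KLF1, in all 3 clones. Within chromosomes, macrophage, hepatocyte and epithelial, and neuronal and glial genes did not pass an approximate Mantel-Haenszel test. An exact stratified test, chosen after that result was seen, gave adjusted p = 0.0617, 0.0362 and 0.0497, so the calls for the last 2 lists depended on the test. Without clone 1 the 3 lists' Fisher's exact adjusted p was 1 for each and without clone 2 it was 1, 0.801 and 0.801, but so few genes were then called that lists of this size could not pass even with 0 members. No member of the 19 lists had a gene-end peak in a control line, the ribosomal protein genes included.

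**Figure D2:**
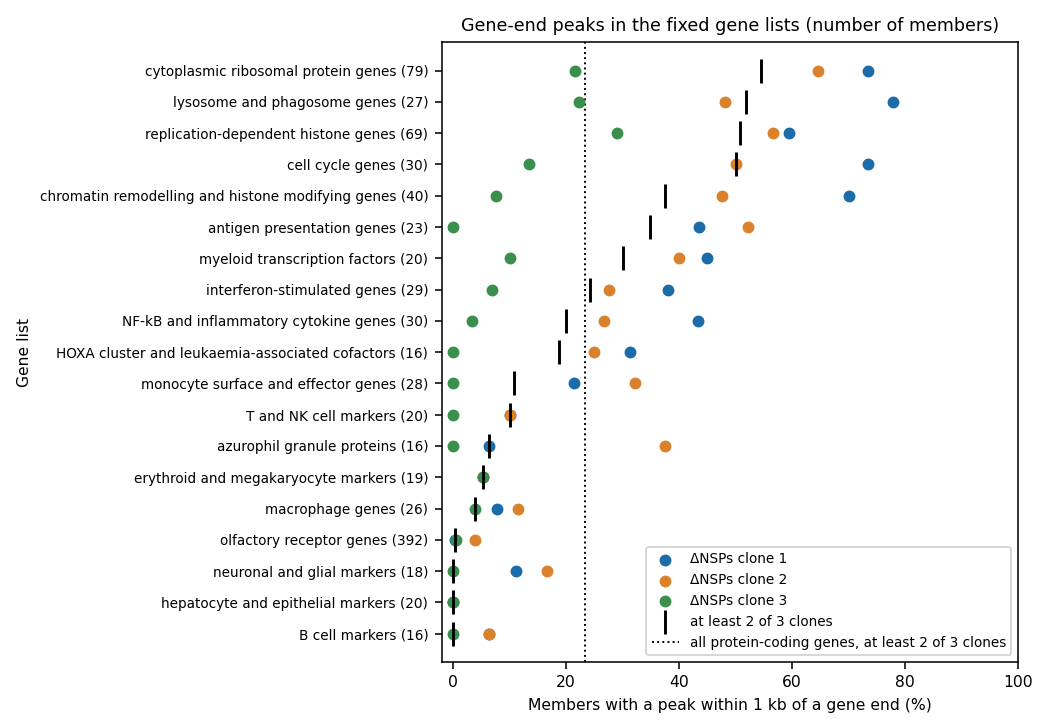
Percent of the members of each fixed gene list with a gene-end peak in each ΔNSPs clone (points), with the percent in at least 2 of 3 clones (vertical ticks) and the same percent over all 19974 protein-coding genes (dotted line at 23.3%); the number of members is in parentheses. Ribosomal protein genes reach 54.4% and olfactory receptor genes 0.255% in at least 2 clones.

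Away from gene ends, 413 of the 1253 regions shared by all 3 clones (33.0%) lay over 1000 bp from any end of a protein-coding or long non-coding gene. The best ranked was on chromosome 17, at 43251572 to 43251919, between genes and 20444 bp from CCDC200, with folds of 3.45, 5.28 and 2.57 in clones 1, 2 and 3. Next came chromosome 2, 172513811 to 172514324, 7581 bp from ITGA6, the gene of integrin alpha 6, with folds of 2.74, 5.79 and 1.99. The implied background in clones 1, 2 and 3 was 46.2, 37.1 and 54.3 reads at the first region. At the second it was 70.6, 56.0 and 88.0 reads. Both lay far above the medians of 5.90, 3.55 and 7.19 reads over each clone's peaks. A high rank there goes with many local reads and does not by itself mean a high fold. A region within THRAP3, at chromosome 1, 36224111 to 36224499, had folds of 7.16, 5.22 and 2.98. A region within IDI1, at chromosome 10, 1048911 to 1049448, had folds of 4.46, 6.03 and 3.28. Exons and introns were not told apart.

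Peaks of the clones were spread unevenly over some chromosomes, a pattern chosen for description after its values were seen. On chromosome 1 from 210 Mb onwards, clones 1, 2 and 3 had 128, 1175 and 138 peaks, and the number in clone 2 was 9.18 times that in clone 1, against 1.39 times before 210 Mb. On chromosome 21 the numbers were 121, 810 and 67, and on chromosome 8 they were 603, 204 and 50. On chromosome 5 before 40 Mb they were 79, 176 and 87, where clone 3 had 1.10 times the number in clone 1, against 0.0854 times in the rest of that chromosome. Of peaks on chromosome 1, the share touching a gene-end window was lower from 210 Mb onwards than before it in clone 2 (12.9% against 29.0%, exact 95% intervals 11.07 to 14.99 and 27.0 to 31.0) and in clone 3 (21.7% against 53.4%, 15.2 to 29.6 and 46.3 to 60.4). In clone 1 the shares were 54.7% and 49.8%, with overlapping intervals. Left without chromosomes 13, 15, 20 and 21 and the named parts of chromosomes 1 and 5, 5777 regions and 4053 genes had a peak in at least 2 clones and no control line. Chromosomes 8, 19 and X were uneven too and stayed in that count; without them as well, 4969 regions and 3458 genes were left.

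**Figure D3:**
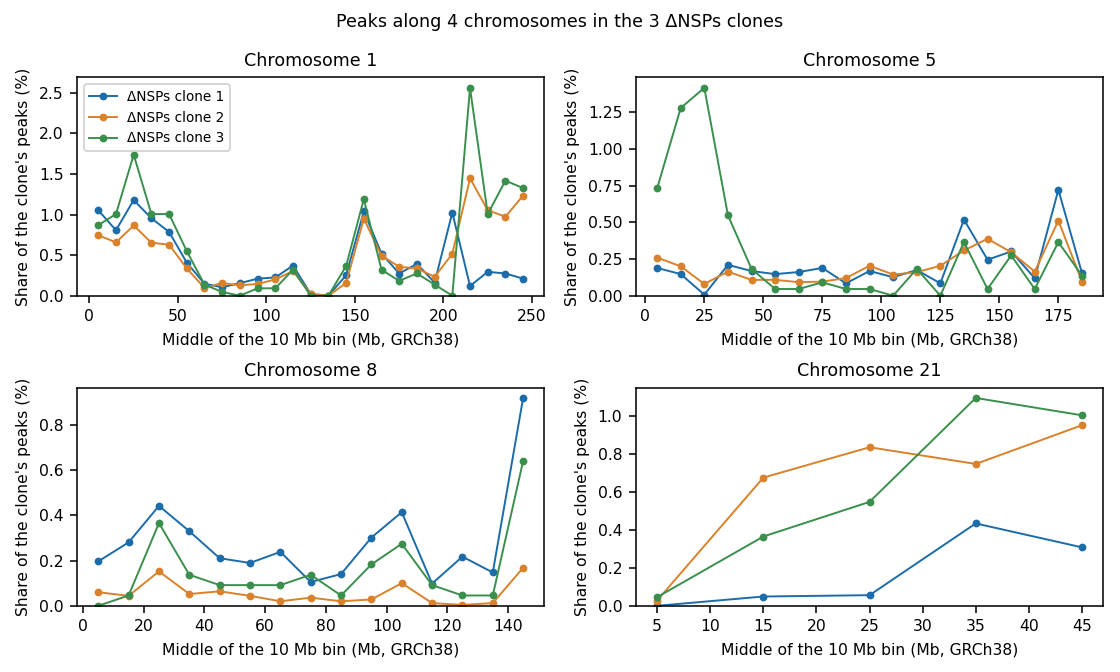
Share of each ΔNSPs clone's peaks in 10 Mb bins along chromosomes 1, 5, 8 and 21, against the middle of the bin in Mb on GRCh38; each line is a clone. Clones 2 and 3 rise on chromosome 1 from 210 Mb, clone 3 on chromosome 5 before 40 Mb, and clone 2 is low along chromosome 8.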

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

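The signals in this part were looked for by a rule set before the data were examined, and no explanation was tested for either. Outside the chromosomes used in the comparisons, clone 2 had 2 peaks on the mitochondrial genome, where the control lines and clones 1 and 3 had none. It also had 69 peaks on unplaced or unlocalised sequence, against at most 23 in a control line and 18 and 12 in clones 1 and 3, although these were 0.283% of its peaks with the mitochondrial ones included, against 63.9 to 83.3% in the control lines.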

How the results depend on the processing

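Added after seeing the data were the summit windows, the stratified tests, the overlap of control peaks over all sequences and the removal of uneven segments. Peak number, covered length and genes per library kept their direction in every alternative run, at the smallest p possible. With a replicate block the differences on the log10 scale stayed at 3.19, 3.23 and 3.49, with an exact sign-flip p of 0.25, the smallest that 3 pairs allow. The labels do not say that a number marks a shared batch, so the numbers were not taken as pairs; same-numbered libraries correlated at 0.00301, 0.00829 and -0.0318 over regions, which tests nothing, since 16 of 32822 regions held a control peak. With −log10 q of 5 or more, 2725 regions, 2189 genes, 2 lists more often and 1 less often were left, and clone overlap was 201-fold over chance. With fold of 5 or more, 225 regions and 135 genes were left, and 135 values of named genes moved over all settings. An overlap of 50% gave 3367 regions, a mean clone overlap of 32.2% and 413-fold over chance; placement by class gave 23.7-fold. Requiring all 3 clones gave 1253 regions, 1079 genes and 2 and 1 lists, and equally long lists 1092 regions, 978 genes and 1 and 1 lists. The lower counts of regions and genes follow from fewer peaks or a stricter rule. Why lists were no longer called more often was not tested. With so few genes called the macrophage, hepatocyte and epithelial, and neuronal and glial lists could not pass even with 0 members (lowest unadjusted exact p 0.107 to 1). Leaving out a clone gave 1439 to 6396 regions, 1124 to 4446 genes, 2 to 4 lists more often and 1 to 4 less often. Leaving out a control line gave 6872 to 6873 regions and 4652 genes. With Mantel-Haenszel chi-square tests within chromosomes and within gene density, 4 lists stayed more often and 1 less often each. The macrophage, hepatocyte and epithelial, and neuronal and glial lists then had an adjusted p of 0.110 each within chromosomes and of 0.0852, 0.0578 and 0.0989 within gene density. Exact tests over the same strata, chosen after those values were seen, kept 4 lists more often, with 3 less often within chromosomes and 5 within gene density. The 3 lists then had an adjusted p of 0.0617, 0.0362 and 0.0497, and of 0.0404, 0.0118 and 0.0404, so 5 of these 6 calls depended on the approximation, and macrophage genes within chromosomes passed neither test. B cell markers newly passed within gene density (0.0404). With a window of 2500 bp, neuronal and glial markers no longer passed (odds ratio 0.158, adjusted p 0.111), although the lowest unadjusted exact p was 0.00590, while chromatin genes (odds ratio 2.44, adjusted p 0.0197) and B cell markers (0.0226) newly passed. Of 209 list tests under an alternative, 158 kept direction and side of the threshold, 33 no longer passed and 3 newly passed. The other 15 odds ratios crossed 1, in lists that passed in neither setting; the cause was not tested. They were 0.290 for interferon-stimulated and 0.658 for chromatin genes at −log10 q of 5 or more. In all 3 clones they were 0.922 for myeloid transcription factors, 0.625 for interferon-stimulated and 0 for antigen presentation genes. With equally long lists they were 0 for interferon-stimulated, 0.883 for antigen presentation and 1.08 for erythroid and megakaryocyte genes, and within gene density 0.981 for interferon-stimulated genes with either test. Leaving out a clone gave 0.883 to 1.68 for myeloid transcription factors, 0.539 to 1.24 for interferon-stimulated and 0 to 1.86 for antigen presentation genes. Histone and olfactory receptor genes passed in every alternative run. Motif enrichment and stratification by promoter GC were not run, for want of a sequence. Unknown read totals and the stricter p of the control lists limit what a missing control peak means.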

Other observations

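The tests in this part on families, control peaks, chromosomes and splits of the libraries were chosen after the results were seen; the test on the short list of clone 3 was set before. Genes were grouped into 55 families of at least 30 members by the root of their symbols. Of these, 14 had gene-end peaks in at least 2 clones more often than other genes and 11 less often (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05). WD repeat genes (WDR) had peaks at 30 of 58 genes (odds ratio 3.55, Fisher's exact adjusted p = 4.71e-05) and translation initiation factors (EIF) at 28 of 55 (3.43, adjusted p = 0.000111). Centrosomal proteins (CEP) had 20 of 39, RNA helicases (DDX) 19 of 37, vacuolar sorting proteins (VPS) 18 of 35 and RNA-binding proteins (RBM) 19 of 39, each above other genes in 3 of 3 clones. Keratin-associated proteins (KRTAP) had 1 of 94 (Fisher's exact adjusted p = 4.04e-08), keratins (KRT) 0 of 55, beta-defensins (DEFB) 0 of 39, cytochromes P450 (CYP) 2 of 56, interleukins and their receptors (IL) 6 of 85 and collagens (COL) 3 of 44. Members of several families lie side by side, so they are not independent, and the ribosomal protein (RPL, RPS) and histone families among the 14 hold genes of the fixed lists.

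Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 6872 regions called on one side only, and the highest other gave 5151. For genes, 1 of 10 gave as many as 4652, and the highest other gave 3368. With 10 splits the share cannot fall under 0.05.

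Few peaks were called in the control lines, also at genes that all cells use. A lower sequencing depth cannot be told apart from other causes. The test took the background implied at regions called in both groups, per bp of the shortest peak. The lowest median log2 ratio of control to clone was -0.51, against clone 2 (7 clone peaks, SD 0.492). The standard error of 0.186 used in the test is that of a mean and not of a median. This median lay above the bound of -1 that a lower depth would need, but every region was chosen by a call in a control line. Most are repeated or unplaced sequence, the shortest peak only stands in for the unknown extension length of the peak caller (without it the medians were -0.12, 0.22 and -0.41 against clones 1, 2 and 3), 2 of the 7 values lay under the bound (-1.09 and -1.47), and test and bound replaced a first version after its result. A loss of signal over background may be involved: 0 of the 58 ribosomal protein and cell cycle genes with peaks in 2 clones or more had a control peak, but only 1 gene had a control gene-end peak at all, so this count was nearly fixed. Depletion of the proteases cannot be told apart from such a difference between library preparations, since the groups coincide with it and the exact permutation p of 0.1 is the smallest possible.

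Clone 3 had the shortest list of the clones. Clone 1 gene-end peaks that clone 3 shared had a higher −log10 q in clone 1 than those it did not share, with a probability of 0.744 (medians 8.72 and 4.83, 957 and 6431 peaks). A lower detection of the same sites in clone 3 is a candidate explanation, but strong peaks may be shared more often whatever the cause. No like value is given for another pair of clones. The probability therefore cannot separate lower detection from a biological difference between clones, which was not tested. The lowest implied background was 1.41 reads in clone 3, not below the 1.22 reads of clone 1. It gave no sign of a lower depth than in clone 1, but it also depends on the unknown extension length.

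Peaks were unevenly spread over chromosomes in clones 2 and 3. A bias of detection with gene density was argued against as the whole cause: the ratio of clone 2 to clone 1 peaks had a Spearman rho of -0.30 with genes per 10 Mb bin (282 bins, permutation p = 1e-05, the smallest possible), and the share of its variance between chromosomes was 51.5% before and 53.7% after removing that trend; for clone 3 over clone 1 rho was 0.197 (282 bins, permutation p = 0.00087) and the shares were 22.4% and 19.8%, against 7.81% in shuffled bins (permutation p = 0.001, the smallest possible). Copy number differences, tested for clone 2 only, cannot be told apart from other causes, since its ratio to clone 1 followed the implied background only weakly (rho 0.150, Pearson 0.181, permutation p = 0.019, 244 bins, which are not independent). Reads stacked outside accessible sites in such segments may contribute. The gene-end share of clone 2 peaks was 16.0 percentage points lower on chromosome 1 from 210 Mb onwards than before it. That share cannot separate such reads from accessible sites away from gene ends, and the segment was chosen after its values were seen. No biological explanation that the design names was tested here.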
